A study of Drosophila melanogaster with 52 samples.

How the data were processed

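Poly(A) RNA from imaginal discs and brains of Drosophila melanogaster larvae in the third instar was measured by paired-end RNA-Seq in 10 libraries, grouped by their labels into 3 wild-type (WT), 4 Spps mutant (SppsKO) and 3 pho mutant (PhoKO) libraries. Per the labels' protocols, libraries were made with a kit that keeps strand and were pooled for 1 sequencing run. Those protocols speak of 12 pooled libraries, of which 10 were analysed here. The series also holds 42 ChIP-Seq samples, which were not analysed here. No label says that libraries of a group came from separate crosses or dissections, so p-values measure the spread between these libraries, which may be partly technical.

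The deposited values are FPKM per gene, normalized across libraries before deposit. Per the submitters' processing notes, the tools used in the series were Trim Galore, Bowtie 1.1.2, SAMtools, SICER 1.1, MACS2 2.1.1, TopHat2 2.1.1, Cufflinks, Cuffnorm, HTSeq and DESeq2, with the genome builds dm3 and BDGP5; which tool made which value, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands, and near-identical copies or repeated genes such as ph-p and ph-d, Cyp4p1 and Cyp4p2, p24-2, Sdic3 and the histone genes, can therefore share fragments, and their values are uncertain. The table lists 16502 genes by symbol, of which 1382 are at 0 in every library. Of the symbols, 16299 matched a current symbol of the Release 6 plus ISO1 MT assembly directly or through a unique synonym. That assembly differs from the build of the files, so it was used only for names and for the order of neighbouring genes.

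FPKM is not a count, so total depth is unknown. The size of the FPKM steps among genes under 0.3 FPKM gave relative depth: taking the first WT library as 100%, the other libraries lay between 59.9% (WT 3) and 106% (SppsKO 3), with PhoKO 1 at 63.8%. Both shallow libraries have coarser low values, and each count of changed genes was repeated without them, an alternative chosen after seeing the data.

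Values were taken as log2(FPKM + 1). A gene was tested when its FPKM was 1 or more in at least 3 libraries, which left 9748 genes. All 10 libraries entered 1 linear model fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend and robust), with no covariate. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. Checked on simulated data with 200 changed genes among the 9748, the fit recovered 79.1% of genes changed by 0.5 on the log2 scale in SppsKO versus WT, 74.6% in PhoKO versus WT and 82.1% in PhoKO versus SppsKO. For genes changed by 2 the shares were 95.5%, 98.5% and 98.5%. False calls were 7 of 177, 7 of 186 and 9 of 189. The simulated noise was normal, independent between genes and drawn with the variances of the fit. Recovery in the real data, where genes are correlated, may therefore differ.

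Before the data were examined, 34 gene lists were written down, of which 33 had a tested member and 31 had the 3 or more needed for a list test. Lists were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 31 lists. Members called were also counted with p-values adjusted over the list alone. Some genes are members of more than 1 list, so counts of different lists are not independent. Examples are gcm (Polycomb targets and glia), ro (Polycomb targets and eye), vkg (hemocyte and glia) and wg (ligands and disc epithelium). Genes named in the text follow a rule fixed at the same time: both targeted genes and the Hox genes; among called genes whose libraries did not overlap between the groups and whose mean was 2 FPKM or more, the 10 largest rises and 10 largest falls with a symbol other than a bare CG or CR number and the largest of each kind whatever the symbol; up to 4 members of each list in order of adjusted p; for PhoKO versus SppsKO, the 5 largest rises and falls; and up to 10 Polycomb target transcription factors called in both mutants. A gene that the rule names in both mutants, whose symbol holds a string of digits, is not reported here.

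Both mutants were compared with the same WT libraries, so the overlap and covariance of their fold changes were set beside 100 simulated sets of unchanged groups, made by recombining the residuals of the fit so that correlation between genes was kept. The alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a common sum, fits of the 2 compared groups only, array weights, eBayes without trend and robust, the replicate number as a block, and leaving out each library in turn. Histone genes were almost all below the filter, with 1 of 93 tested, and the list of mitochondrial transcripts matched 0 genes.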

Results

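Transcript levels were compared between wild-type larvae and larvae lacking one of a pair of DNA-binding proteins, Spps and Pho, that recruit Polycomb group complexes to chromatin. Polycomb complexes keep developmental genes silent, so the comparison asks which genes change expression when a recruiter is lost. Per the series' design text, Spps mutants lacked both maternal and zygotic product and pho mutants lacked zygotic product. The tissue was imaginal discs and brains of larvae in the third instar, measured in 3 WT, 4 SppsKO and 3 PhoKO libraries. Between 9269 and 9537 genes reached 1 FPKM in each library.

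The targeted genes followed the labels in every library. Spps stood at 12.5 ± 0.335 FPKM (SD, n = 3) in WT and 0.957 ± 0.0743 (SD, n = 4) in SppsKO, which is 7.67% of the WT mean (exact two-sided permutation test, p = 0.0286, the smallest that 35 arrangements allow). The gene pho stood at 59.6 ± 7.33 FPKM (SD, n = 3) in WT and 17.5 ± 1.86 (SD, n = 3) in PhoKO, which is 29.3% of WT (exact two-sided permutation test, p = 0.1, the smallest that 3 libraries against 3 allow). In the limma fit Spps fell by 2.78 on the log2 scale in SppsKO (SE 0.06, adjusted p = 1.71e-09) and pho fell by 1.71 in PhoKO (SE 0.10, adjusted p = 5.53e-06). Neither gene was called in the other mutant. The labels do not say which part of either gene was removed, so remaining fragments from an intact part are possible. The pho-like paralog phol was not called in either mutant, with adjusted p = 0.635 in SppsKO and 0.0871 in PhoKO.

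**Figure D1:**
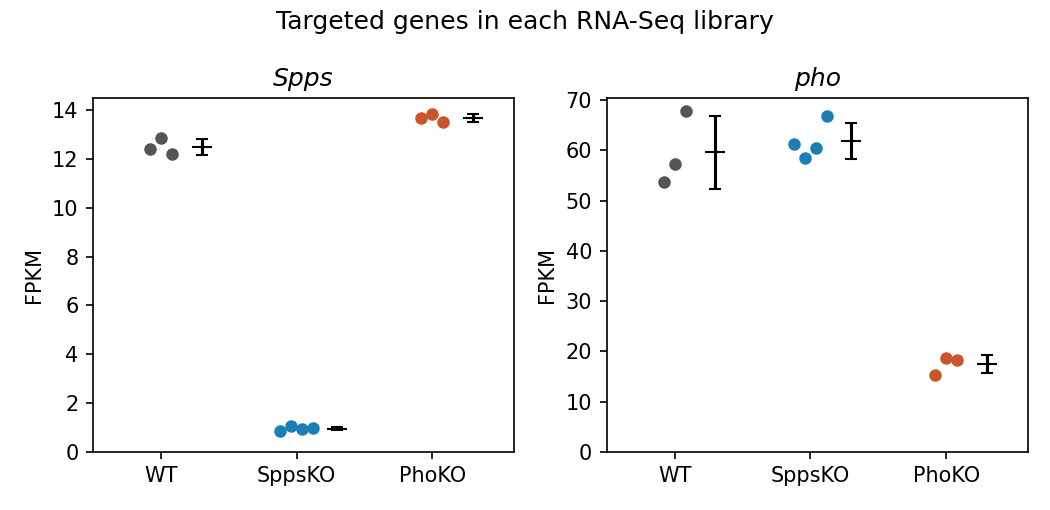
FPKM of Spps (left) and pho (right) in each library, with points for libraries and bars for the group mean ± SD beside them. Spps lies between 0.877 and 1.04 FPKM in the 4 SppsKO libraries and at 12.2 or more in all others, and pho lies between 15.3 and 18.7 FPKM in the 3 PhoKO libraries and at 53.7 or more in all others.

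Libraries grouped by genotype on the first and second principal components, but less clearly by correlation. The first principal component of the tested genes, with 29.1% of the variance, separated SppsKO from the rest, and the second, with 19.0%, separated PhoKO. The third, with 17.9%, spread libraries within groups, with WT 2 and SppsKO 4 at one end. At its other end lay both shallow libraries, PhoKO 1 (-23.8) and WT 3 (-15.0). Correlations of log2(FPKM + 1) across genes, which are not independent replicates, lay between 0.962 and 0.995 within groups and between 0.942 and 0.974 between groups. These ranges overlap, and the median correlation of PhoKO 3 was 0.965 both with its own group and with the other groups.

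The Hox genes, the classical Polycomb targets that set segment identity, were not called in either mutant. Of 8 Hox genes 7 were tested, and pb was below the filter. The fold change of Ubx was -0.24 in SppsKO (SE 0.12, adjusted p = 0.265) and 0.18 in PhoKO (SE 0.13, adjusted p = 0.449). Values of abd-A were -0.25 (SE 0.13) and -0.30 (SE 0.14), those of Scr 0.12 (SE 0.12) and 0.38 (SE 0.13), and those of Antp -0.02 (SE 0.04) and 0.12 (SE 0.04), in SppsKO and PhoKO. The remaining values were 0.15 and -0.12 for lab, -0.07 and -0.03 for Dfd, and -0.07 and -0.03 for Abd-B. Signs of Dfd, Antp and Abd-B in SppsKO turned under quantile normalization, and signs of Abd-B and, in PhoKO, Dfd turned when single libraries were left out, with the values in the closing part. By limma, 0 Hox genes were called adjusted over the list alone in either mutant, and at an unadjusted p under 0.05 the counts were 0 in SppsKO and 2 in PhoKO. The median in PhoKO was -0.03 while camera gave the direction as higher (adjusted p = 0.79), so these differ in sign. With these standard errors, small changes in a part of the tissue would not be detectable.

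Known Polycomb target transcription factors moved in both directions. Of 86 tested members, 4 rose and 3 fell in SppsKO, and 10 rose and 8 fell in PhoKO. Among all tested genes 8.18% were called in SppsKO and 9.66% in PhoKO. The share of the list was near that value in SppsKO and above it in PhoKO. No test compared these shares. Adjusted over the list alone, the counts were 4 and 3 in SppsKO and 13 and 9 in PhoKO. In SppsKO the POU factor gene pdm2 rose by 0.75 (SE 0.09, adjusted p = 0.000629), the segment polarity gene gsb by 0.63 (SE 0.09), gcm, which directs glial fate, by 0.40 (SE 0.06), and Doc3 by 0.37 (SE 0.07). In PhoKO the retinal determination genes eya and so rose by 0.42 (SE 0.05) and 0.36 (SE 0.05), sna by 0.45 (SE 0.06) and eyg by 0.42 (SE 0.06). Called in both mutants were gsb, lower in PhoKO (-0.42, SE 0.10), ro, lower in SppsKO (-0.35, SE 0.09) and higher in PhoKO (0.42, SE 0.10), and gcm, higher in both. The direct comparison called gsb (adjusted p = 0.000118) and ro (adjusted p = 0.00076). As a set the list was not called by camera, with adjusted p = 0.51 in SppsKO and 0.281 in PhoKO. Camera tests for a shift in 1 direction, so a list that moves both ways can escape it. Fry in its mixed form, which ignores direction, gave adjusted p = 0.000219 in SppsKO and 9.03e-08 in PhoKO. That form does not compare the list with other genes. The PhoKO calls of gsb, ro and gcm and the SppsKO call of ro each ended when any of several single libraries was left out, WT 1 among them (highest adjusted p = 0.127). Of all tested genes 14.4% were called in the direct comparison, which called 14 members higher in PhoKO than in SppsKO and 11 lower. Adjusted over the list alone these counts were 17 and 14, and camera did not call the list (adjusted p = 0.691). Besides ro, those higher included eya (0.33, SE 0.05) and sna (0.41, SE 0.06), and besides gsb, those lower included pdm2 (-0.63, SE 0.09) and Doc3 (-0.58, SE 0.07). The number higher was 9 without SppsKO 2 and 8 without PhoKO 2. In SppsKO 7 rose without PhoKO 1, and the number that fell was 0 without WT 1 or WT 2 and 1 without SppsKO 1 or SppsKO 2. In PhoKO the number that rose was 5 without WT 1, 6 without WT 2, PhoKO 1 or both shallow libraries.

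Among 29 Polycomb group genes, 3 besides Spps fell in SppsKO, and in PhoKO 2 rose and pho fell, with the same counts adjusted over the list alone. The number that rose in PhoKO was 4 without SppsKO 4. In PhoKO ph-d rose by 0.62 (SE 0.06, adjusted p = 0.000166) and ph-p by 0.52 (SE 0.08, adjusted p = 0.00335). These are near-identical neighbouring genes encoding Polyhomeotic, so fragments may be split between them. In SppsKO Dsp1 (-0.21, SE 0.05), ph-d (-0.21, SE 0.05) and Su(z)2 (-0.28, SE 0.07) were called, and these 3 calls were lost when WT 1, among other libraries, was left out (highest adjusted p = 0.144). Camera called the list higher in PhoKO (adjusted p = 0.0204), a call lost without PhoKO 3 (adjusted p = 0.113) and with an estimated correlation (adjusted p = 0.924), and fry did not call it (adjusted p = 0.157). In SppsKO fry called it lower (adjusted p = 0.0108), with Spps itself a member, and camera did not (adjusted p = 0.744). By limma 0 trithorax group genes were called in SppsKO (3 at an unadjusted p under 0.05), and Bap60 alone of 23 was called in PhoKO (-0.18, SE 0.04, adjusted p = 0.0253), a call lost without WT 1, WT 2, PhoKO 1 or PhoKO 2.

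In SppsKO versus WT, limma called 797 of 9748 genes, with 382 higher and 415 lower, and 156 changed by 1 or more on the log2 scale (48 higher, 108 lower). Under quantile normalization 625 were higher and 307 lower, so the balance of directions turned with the scaling. The gene mthl8, of the Methuselah-like receptor family, was at 0.00699 FPKM or less in WT and at 10.8 ± 0.669 (SD, n = 4) in SppsKO. The transcription factor gene HLH3B rose from 2.54 to 13.1 FPKM (log2 fold change 1.99, SE 0.12, adjusted p = 8.35e-06) and the anoctamin-family channel gene subdued from 10.1 to 40.8 (1.91, SE 0.10, adjusted p = 5.15e-06). Cyp6a17 rose from 0.0616 to 3.55 FPKM, IM18 by 1.72 (SE 0.27) and Ady43A by 1.53 (SE 0.07). The cytochrome P450 genes Cyp4p2 and Cyp4p1 fell by 6.26 (SE 0.42) and 3.73 (SE 0.15), Crg-1 fell by 2.26 (SE 0.11), the sodium channel gene ppk13 by 2.06 (SE 0.18) and Ela by 1.88 (SE 0.30). The largest fall, whatever the symbol, was that of CG14850, from 511 ± 312 FPKM (SD, n = 3) to 0.148 ± 0.119 (SD, n = 4). It was also low in PhoKO, at 0.658 ± 0.948 FPKM (SD, n = 3), with a log2 fold change of -8.24 (limma adjusted p = 2.99e-05). The direct comparison did not call CG14850 (adjusted p = 0.591), so it set WT apart from both mutants. Short RNA genes (snRNA:U2:34ABa 3.12, snoRNA:Psi28S-2648 2.74, and snoRNA:Psi18S-1086, listed at 0 in every WT library) were called higher, but poly(A) libraries measure them poorly. The calls of both snoRNA genes, of Muc68Ca (-3.10) and of CecC (15.2 FPKM in WT, 3.23 in SppsKO) were each lost when 1 library was left out (snoRNA:Psi28S-2648 without SppsKO 2, CecC without WT 1, the others without any of several, WT 3 among them). The count was 508 without SppsKO 2 and 2263 with array weights.

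Blood cell genes were lower in SppsKO. Of 16 hemocyte markers 8 fell and 0 rose, and adjusted over the list alone 10 fell and 3 rose. The crystal cell enzymes PPO2 and PPO1, prophenoloxidases of melanization, fell by 2.47 (SE 0.26, adjusted p = 0.00103) and 2.48 (SE 0.33, adjusted p = 0.00336), PPO1 from 47.8 ± 19.8 FPKM (SD, n = 3) to 7.53 ± 2.51 (SD, n = 4). The collagen genes Cg25C and vkg, which blood cells and fat body secrete, fell by 0.86 (SE 0.12) and 0.83 (SE 0.13). Camera called the list lower (adjusted p = 0.000428 at the preset correlation, adjusted p = 0.932 with an estimated correlation) and so did fry (adjusted p = 0.0254). Markers of other larval tissues also had medians below 0, at -1.79 for salivary gland, -0.63 for muscle, -1.52 for gut and Malpighian tubule and -0.57 for fat body, with 0 members called in these lists. At an unadjusted p under 0.05 their counts were 4, 5, 3 and 2. Camera called the first 3 lower (adjusted p = 0.00197, 0.000428 and 0.0222), and none with an estimated correlation (adjusted p = 0.932 for each), and fry called none of them (adjusted p = 0.226, 0.243 and 0.226). The call for gut and Malpighian tubule ended without WT 1, WT 2 or SppsKO 4. The member count was 4 without WT 1, SppsKO 1, SppsKO 2 or SppsKO 3, 5 without WT 3, and 4 without both shallow libraries.

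Ring gland genes were lower too. Of 11 members 4 fell in SppsKO and 5 adjusted over the list alone. The ecdysone synthesis gene sro fell by 0.87 (SE 0.11, adjusted p = 0.00155) and sNPF, a neuropeptide gene, by 0.53 (SE 0.08, adjusted p = 0.0026). Members spok (-0.32, SE 0.08) and nvd (-0.47, SE 0.12) were called, and both calls ended without WT 2, among other libraries. Camera called the list lower (adjusted p = 0.0008 at the preset correlation, adjusted p = 0.932 with an estimated correlation), and so did fry (adjusted p = 0.0284). Without WT 2, WT 3, SppsKO 1, SppsKO 2, SppsKO 3 or PhoKO 3 the member count was 2.

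Other list members moved singly. Among 13 detoxification genes 2 rose and 1 fell in SppsKO, and adjusted over the list alone 2 rose and 3 fell. GstD9 and GstE8 rose by 1.14 (SE 0.11) and 1.12 (SE 0.09) and GstE1 fell by 1.31 (SE 0.10). In PhoKO GstE8 (0.84, SE 0.10) and GstE9 (0.77, SE 0.20) were called higher and GstE5 (-0.53, SE 0.13) lower, the same counts adjusted over the list alone, and the calls of GstE9 and GstE5 ended without WT 1, among other libraries. The eye colour gene ry, a common marker of laboratory stocks, rose in SppsKO by 1.43 (SE 0.08, adjusted p = 5.15e-06), from 1.79 to 6.51 FPKM, and was not called in PhoKO (-0.11, SE 0.08). The chitin-binding protein gene obst-A rose in SppsKO by 0.64 (SE 0.08), the proneural gene ato by 0.29 (SE 0.04) and the Notch-modifying glycosyltransferase gene fng by 0.21 (SE 0.04).

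In PhoKO versus WT, limma called 942 of 9748 genes, with 447 higher and 495 lower, and 128 changed by 1 or more on the log2 scale (63 higher, 65 lower). The largest rise was that of p24-2, from 0.0338 to 29.7 ± 9.57 FPKM (SD, n = 3; 4.85, SE 0.18, adjusted p = 3.52e-07). Cyp6a17 rose by 3.72 (SE 0.24), mthl8 by 3.36 (SE 0.07), the cuticle gene Lcp65Ac by 3.21 (SE 0.58), IM18 by 1.82 (SE 0.29), the phagocytosis receptor gene NimC1 by 1.64 (SE 0.16), Ady43A by 1.63 (SE 0.07) and Sdic3, one of a repeated gene cluster, by 1.57 (SE 0.16). The salivary glue gene Sgs4 fell by 5.77 (SE 0.99), the ionotropic receptor gene Ir76a by 2.35 (SE 0.11), Crg-1 by 2.32 (SE 0.12), lectin-28C by 2.31 (SE 0.28), hng3 by 1.64 (SE 0.08), Cyp4p2 by 2.49 (SE 0.45) and Cyp4p1 by 1.59 (SE 0.17). CR40469 had the largest fall whatever the symbol, from 869 ± 192 FPKM (SD, n = 3) to 0.854 ± 0.26 (SD, n = 3), and stood at 1.16 ± 0.121 (SD, n = 4) in SppsKO. The antimicrobial genes CecA1 (-2.14) and AttD (-1.87) lost their calls without WT 2, among other libraries, and snRNA:U2:34ABa (2.14) without WT 1, WT 3 or PhoKO 3. Calls of Sgs4 and Cyp4p2 were lost without both shallow libraries. The count was 566 without WT 1, 593 without PhoKO 2, 471 when only WT and PhoKO were fitted and 2178 with array weights.

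Eye and glia genes were higher in PhoKO. Of 13 eye markers 7 rose and 0 fell, and adjusted over the list alone 8 rose and 1 fell. The proneural gene ato rose by 0.54 (SE 0.04, adjusted p = 3.46e-05) and gl, a photoreceptor transcription factor gene, by 0.62 (SE 0.08, adjusted p = 0.00112), beside eya and so. Of 15 glia markers 7 rose and 0 fell, the same counts adjusted over the list alone, led by the sodium pump subunit gene nrv2 (0.41, SE 0.04, adjusted p = 0.000396), the glial determinant repo (0.33, SE 0.06), axo (0.34, SE 0.06) and loco (0.22, SE 0.05), the last not called without WT 1, PhoKO 1 or PhoKO 3. Camera called both lists higher (adjusted p = 3.52e-05 for eye and 0.00192 for glia), but neither with an estimated correlation (adjusted p = 0.304 and 0.475). Fry called both (adjusted p = 0.000638 and 0.0229). In SppsKO ato rose and ro fell among eye markers, and gcm rose and vkg fell among glia markers. Adjusted over the list alone, 4 eye markers rose and 2 fell in SppsKO, and 1 glia marker rose and 2 fell. The eye count was 4 without WT 2, PhoKO 1 or PhoKO 3. The glia count was 3 without WT 1, PhoKO 1 or PhoKO 3, 4 without WT 3 or PhoKO 2, and 1 without both shallow libraries, where repo and axo were not called.

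**Figure D2:**
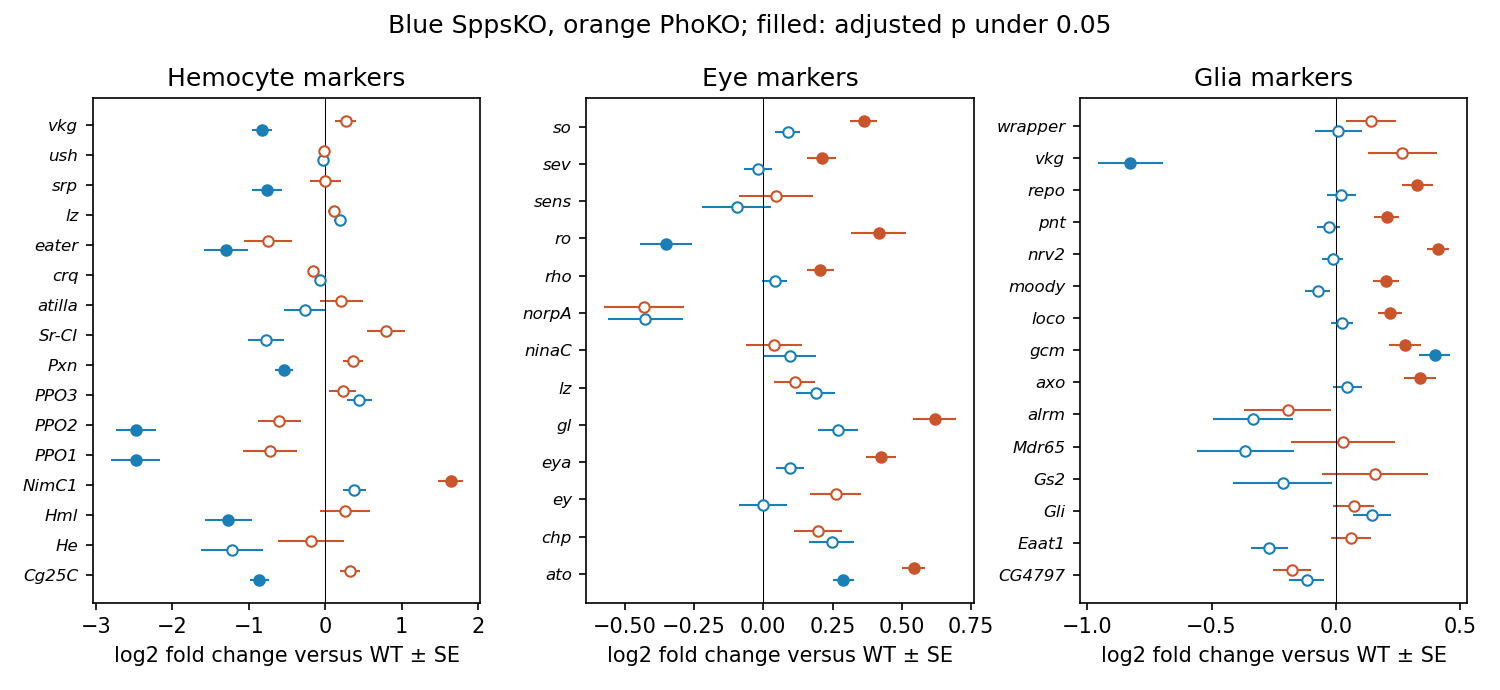
Log2 fold change versus WT (horizontal axes, log2 of FPKM + 1, bars are SE) of each tested hemocyte, eye and glia marker, blue for SppsKO and orange for PhoKO, filled where the adjusted p was under 0.05. Filled blue points lie below 0 for 8 hemocyte markers, and filled orange points lie above 0 for 7 eye and 7 glia markers.

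Notch target genes were lower in PhoKO. Of 13 members 4 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose. Repressor genes of the Enhancer of split complex fell, E(spl)m7-HLH by 0.59 (SE 0.09), E(spl)m8-HLH by 0.39 (SE 0.05) and E(spl)m3-HLH by 0.24 (SE 0.04), while h rose by 0.19 (SE 0.04), a call lost without WT 1, WT 2, PhoKO 2 or PhoKO 3. Camera called the list lower (adjusted p = 0.00263 at the preset correlation, adjusted p = 0.756 with an estimated correlation), and so did fry (adjusted p = 0.0229). In SppsKO 1 member was called, E(spl)m5-HLH (0.24, SE 0.06, adjusted p = 0.0471), a call lost without WT 1, among other libraries, and under median-of-ratios scaling.

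Genes of proliferation and stress signalling were among those higher in PhoKO. In the list of JAK/STAT and JNK responses 4 of 18 rose and 0 fell, namely Gadd45 (0.89, SE 0.13), the cell death gene rpr (0.37, SE 0.05), Socs36E (0.36, SE 0.06) and Mmp2 (0.35, SE 0.05). Of 27 cell cycle genes 6 rose, led by the mitotic phosphatase gene stg (0.38, SE 0.06, adjusted p = 0.00248). Of 15 neuroblast markers 4 rose, led by insc (0.47, SE 0.09, adjusted p = 0.00783). Adjusted over the list alone, 4, 8 and 4 members rose, and 1 of the first list fell. Camera called the 3 lists higher (adjusted p = 0.00909, 0.00284 and 0.0188), and none with an estimated correlation (adjusted p = 0.756, 0.934 and 0.944). Fry called the first (adjusted p = 0.0343) but not the cell cycle or neuroblast list (adjusted p = 0.133 and 0.237). In SppsKO limma called 0 cell cycle and 0 neuroblast genes (3 and 1 at an unadjusted p under 0.05). Fold changes of cell cycle genes lay above 0 for 20 of 27 members in PhoKO and for 19 of 27 in SppsKO. The JAK/STAT and JNK count was 4 whichever library was left out. The cell cycle count was 1 without WT 2, SppsKO 2, PhoKO 1 or PhoKO 2 and 2 without WT 1, SppsKO 1, SppsKO 3 or PhoKO 3, while stg was called in each of these fits, and it was 3 without both shallow libraries. The neuroblast count was 1 without WT 1, SppsKO 1, SppsKO 2, SppsKO 3 or PhoKO 1, 2 without WT 2 or PhoKO 2, and 0 without both shallow libraries. Among the calls that ended without WT 1 were those of the neuroblast genes wor, cas and mira, the replication genes dpa and dup and the cytokinesis gene pav.

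In PhoKO versus SppsKO, limma called 1400 of 9748 genes, with 706 higher and 694 lower. Under quantile normalization 523 were higher and 819 lower, and under median-of-ratios scaling 771 and 629. Besides Spps and pho themselves, p24-2 (4.87, SE 0.17), Cyp4p2 (3.77, SE 0.42), Lcp65Ac (3.41, SE 0.54) and CG32198 (7.17, SE 0.91) were higher in PhoKO, and HLH3B (-2.23, SE 0.12), Ir76a (12.4 FPKM in SppsKO, 2.35 in PhoKO), subdued (-1.92, SE 0.10) and Sgs4 (-3.98, SE 0.93) were lower. The call of Sgs4 ended without SppsKO 4 or any PhoKO library, and that of ng3 (4.01, SE 1.09) without WT 1, among others. Ubx was called higher in PhoKO than in SppsKO (0.42, SE 0.12, adjusted p = 0.0461), a call lost without any 1 SppsKO library, WT 1, PhoKO 2 or PhoKO 3 (highest adjusted p = 0.134). The count was 848 without SppsKO 2, 860 without PhoKO 1, 872 without PhoKO 2 and 2764 with array weights.

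Hemocyte markers were higher in PhoKO than in SppsKO for 9 of 16 members (camera adjusted p = 4.86e-05, adjusted p = 0.633 with an estimated correlation), glia markers for 8 of 15 and eye markers for 7 of 13, and 9, 8 and 8 adjusted over the list alone. For glia and eye markers camera gave adjusted p = 0.000293 and 0.000804, and adjusted p = 0.441 for both with an estimated correlation. Fry called the hemocyte, glia, eye and ring gland lists (adjusted p = 0.00426, 0.00116, 0.00116 and 0.0173) but not the muscle list (adjusted p = 0.121). Ring gland markers were called higher in PhoKO for 6 of 11 members (7 adjusted over the list alone; camera adjusted p = 0.000522, adjusted p = 0.64 with an estimated correlation), a count of 3 without SppsKO 1 or both shallow libraries and 2 without SppsKO 3 or PhoKO 1. Of 19 muscle markers 2 were called higher, the same adjusted over the list alone, and all 19 had fold changes above 0 (median 0.93, camera adjusted p = 0.00011, adjusted p = 0.796 with an estimated correlation). The muscle count was 7 without PhoKO 3 and 0 or 1 without any other library. Other outside tissues went both ways, with a median of -0.81 for salivary gland (6 of 13 above 0, 1 called higher and 1 lower), 0.48 for fat body (9 of 11 above 0) and 0.77 for gut and Malpighian tubule (8 of 11 above 0).

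Notch target genes were lower in PhoKO than in SppsKO for 7 of 13 members and higher for h (0.32, SE 0.04), 8 and 1 adjusted over the list alone. Those lower were all of the Enhancer of split complex, among them E(spl)m8-HLH (-0.39, SE 0.04, adjusted p = 0.000383), E(spl)m7-HLH (-0.44, SE 0.08) and E(spl)m5-HLH (-0.37, SE 0.06). Camera called the list lower (adjusted p = 0.000804, adjusted p = 0.633 with an estimated correlation), whichever library was left out, and so did fry (adjusted p = 0.0065). Of 6 genes often used as stock markers, ry was called lower (-1.53, SE 0.08), the same adjusted over the list alone, and the list was called lower by camera (adjusted p = 0.0338, adjusted p = 0.64 with an estimated correlation) and fry (adjusted p = 0.00116). That camera call ended without SppsKO 1, SppsKO 3 or PhoKO 1. Among Polycomb group genes Su(z)2 (0.54, SE 0.07), ph-d (0.82, SE 0.05) and ph-p (0.53, SE 0.07) were higher besides Spps, and pho was lower. Adjusted over the list alone 5 were higher and 1 lower. Camera called that list higher (adjusted p = 0.0284, adjusted p = 0.64 with an estimated correlation), a call that ended without PhoKO 3. Fry called it higher too (adjusted p = 0.000675). Both mutated genes are members, Spps at 2.91 (SE 0.06) and pho at -1.77 (SE 0.09), so these list results partly restate the genotypes. In the JAK/STAT and JNK list 6 of 18 were higher (7 adjusted over the list alone; camera adjusted p = 0.0338, adjusted p = 0.64 with an estimated correlation; fry adjusted p = 0.0347), a camera call that ended without SppsKO 4 or PhoKO 3. That count was 3 without SppsKO 2 or PhoKO 2 and 2 without PhoKO 3. Of 15 neuroblast markers 5 were higher, the same adjusted over the list alone (camera adjusted p = 0.0338, adjusted p = 0.825 with an estimated correlation, ended without SppsKO 4; fry adjusted p = 0.121). Their count was 1 without PhoKO 1, 2 without SppsKO 1, SppsKO 2 or PhoKO 2, and 3 without WT 1 or SppsKO 3. Of 27 cell cycle genes 7 were higher and 2 lower, 10 and 3 adjusted over the list alone. Neither camera (adjusted p = 0.127) nor fry (adjusted p = 0.238) called that list. The number of cell cycle genes higher was 3 without PhoKO 1 and 4 without SppsKO 2, SppsKO 3 or PhoKO 2. Camera called neuron markers higher (median 0.23, adjusted p = 0.0332, adjusted p = 0.825 with an estimated correlation; fry adjusted p = 0.344), a call that ended without SppsKO 4 or PhoKO 1. The single neuron marker called by limma, cac, was lower (-0.74, SE 0.20), a call lost in 7 of the fits that left out 1 library, WT 1 among them, and adjusted over the list alone limma called 0 (7 at an unadjusted p under 0.05).

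Calls in both mutants went mostly in the same direction. Higher in both were 129 genes and lower in both 128, with 10 in opposite directions. Independent lists of these sizes would share 17.5 higher, 21.1 lower and 38.4 opposite genes. Simulated unchanged groups sharing the WT libraries had means of 2.67 higher, 4.6 lower and 0 opposite genes, and 1 of 100 draws reached as many genes in the same direction. The covariance of the fold changes across genes was 0.0981, against a simulated mean of 0.0383 and a range of -0.0265 to 0.131, and the correlation was 0.527 against a simulated mean of 0.53. Both lie within the range that shared controls give, and 3 WT libraries cannot be split into sets of 2 or more. For the correlation that range was -0.398 to 0.978, too wide to decide. The observed covariance was reached by 8 of 100 draws. The highest simulated counts were 248 higher and 443 lower, so the simulated means rest largely on rare draws. Part of the overlap may thus come from the shared WT libraries. The overlap was 161 without WT 1, 147 with each pair of groups fitted alone and 756 with array weights.

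**Figure D3:**
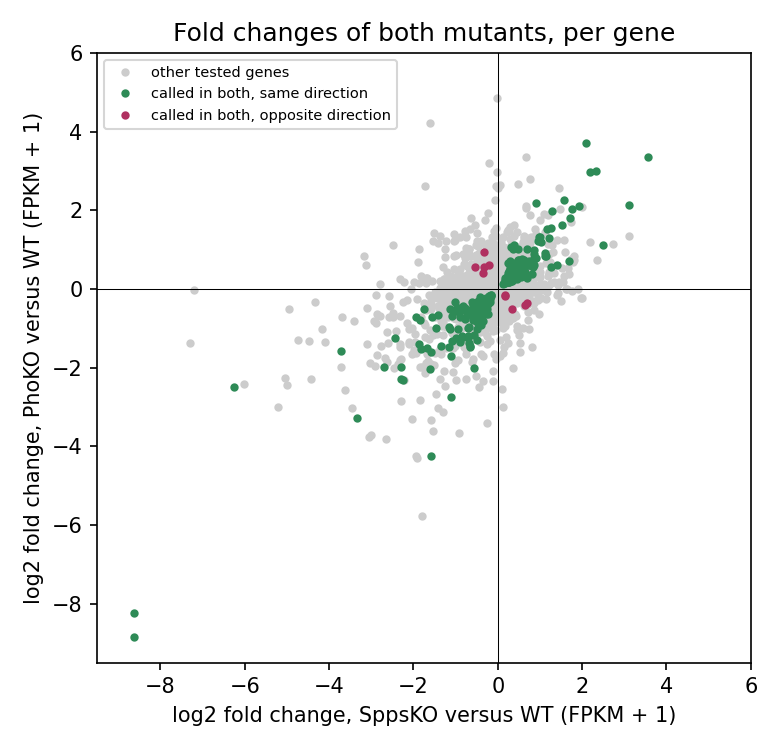
Log2 fold change of each tested gene in SppsKO versus WT (horizontal) and PhoKO versus WT (vertical), with genes called in both coloured by whether the directions match. Of the coloured genes, 257 lie in the quadrants of equal sign and 10 in the others.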

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

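The tests on blood cells, outside tissue, Polycomb targets, brain share and eye disc share were chosen after the results they bear on had been seen, and the ribosomal comparison in the blood cell test was added once its value was known. Among 53 named genes called in SppsKO versus WT, 3 had SppsKO 4 far from the other SppsKO libraries. Distance was measured as its gap to the nearest library over the whole range. Chance alone gives about 5%, but only called genes were screened. A far library widens the spread and makes a call less likely, so 3 of 53 cannot be compared with that rate. The far library was the same each time, and it also lay at one end of the third principal component (20.1). Its median correlation with its own group was 0.972, against 0.986 to 0.988 for the other SppsKO libraries. Cyp4p2 had a ratio of 0.974, with 0.295 FPKM in SppsKO 4 and 0.0461 to 0.0527 in the others. His1:CG33840 had a ratio of 0.974, with 2.65 FPKM against 1.95 to 1.97. Su(z)2 had a ratio of 0.854, with 7.02 FPKM against 8.61 to 8.88.

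Of the 35 splits of the SppsKO and WT libraries into groups of the same sizes, only the real split called as many genes (797, highest other 11). That is the smallest share that 35 splits allow, so arbitrary labelling would rarely give as many. The other splits mix both genotypes within a group, which widens the spread and can lower their counts. The test does not bear on differences in strain or dissection between the groups. The same held for PhoKO versus SppsKO, with 1 of 35 (1400, highest other 1). For PhoKO versus WT 1 of 10 splits called as many (942, highest other 7), and 10 splits are too few for a share under 0.05.

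Hemocyte genes were lower in SppsKO. Fewer blood cells carried over in those dissections cannot be told apart from regulation. Residuals of the 16 genes correlated within groups (mean 0.362, against a median of -0.00404 for 1000 matched random lists). Those of ribosomal protein genes did so too (0.468), so such values are not particular to blood cell genes. Less tissue from outside discs and brain stays open: 5 of 5 lists of salivary gland, fat body, muscle, gut and ring gland genes had a median below 0, but of these limma called members in the ring gland list alone. Salivary gland and gut genes also had low medians in PhoKO (-2.57 and -1.22), where the hemocyte median was 0.16, but within their spread: limma called 1 of 13 and 0 of 11 members (2 and 0 at an unadjusted p under 0.05), camera did not call gut (adjusted p = 0.281), and its salivary gland call ended without WT 3 or PhoKO 3 (highest adjusted p = 0.446), so these medians do not decide. An effect of Spps on blood cell number or gene expression was not tested.

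Genes called in both mutants changed mostly in the same direction. Noise of the shared WT libraries could give the covariance of 0.0981, which lies within the simulated range. Of 100 draws, 8 reached that covariance, but only 1 reached as many genes in the same direction. A WT strain whose genome differs from both mutants may also contribute, but the test cannot decide it. These genes formed 3.34 times as many neighbouring pairs as random sets (22 pairs against a mean of 6.58). The factor was 2.05 for genes called in SppsKO alone and 1.8 in PhoKO alone. Such factors also depend on set size, which was 254, 524 and 674 genes. In each of these sets 0 of 1000 random draws reached the observed pairs, so an excess was not particular to the shared genes. A response of Polycomb target genes common to both mutants stays open, with 1 list member among the 257 genes against 2.27 expected (odds ratio 0.432, 95% interval 0.0108 to 2.5, one-sided Fisher exact p = 0.901).

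Eye and glia genes were higher in PhoKO. A larger share of brain cannot be told apart from other causes. The glia minus neuron score of every PhoKO library lay above every WT library, but by a gap of 0.0527 against a WT SD of 0.0955. The prediction against a larger share asked only for that separation, and comparing the gap with the WT SD was a further requirement. Neuron markers had a median of -0.07 in PhoKO, with 9 of 20 above 0. SppsKO scores ran from -0.0982 (SppsKO 1) to 0.338 (SppsKO 4), wider than the PhoKO range of 0.147 to 0.187. A larger share of eye-antennal discs stays open too: the fold changes of the 13 eye genes scattered more than their standard errors (heterogeneity statistic 108), which genes also expressed outside the eye can do. An effect of Pho loss on these genes was not tested apart from tissue share.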

How the results depend on the processing

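Leaving out both shallow libraries (WT 3 and PhoKO 1) was chosen after seeing the data; the other alternatives were planned. Total counts of called genes stayed within 1.5 times of the reported ones under both pseudocounts, no filter, every scaling and eBayes without trend and robust, but their directions did not: quantile normalization gave 625 higher and 307 lower in SppsKO versus WT (67.1% higher against 47.9%) and 523 higher and 819 lower in PhoKO versus SppsKO (39% against 50.4%). In PhoKO versus WT it gave 548 and 417 (56.8% against 47.5%). Array weights gave 2263 genes for SppsKO versus WT, 2178 for PhoKO versus WT, 2764 for PhoKO versus SppsKO, 756 in both mutants and a covariance of 0.118. Fits of the compared groups alone gave 471 for PhoKO versus WT and 147 in both, and a mean of 5 FPKM or more gave 169 in both, with fewer genes tested. The covariance was 0.201 with a pseudocount of 0.1, 0.0464 with a pseudocount of 5, 0.0718 with no filter and 0.127 without both shallow libraries. With an estimated correlation 0 list tests were called in SppsKO versus WT, 0 in PhoKO versus WT and 0 in PhoKO versus SppsKO. Without both shallow libraries 4 hemocyte, 2 ring gland and 1 glia members were called, with fewer samples. Where no construction is named, the cause was not tested.

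Leaving out each library in turn gave 508 to 842 genes for SppsKO versus WT, 566 to 1112 for PhoKO versus WT, 848 to 1673 for PhoKO versus SppsKO and 161 to 272 in both, and a covariance of 0.0885 to 0.12. Called lists numbered 4 to 8 in SppsKO (4 without SppsKO 4), 9 to 10 in PhoKO and 9 to 12 in the direct comparison. Called members numbered 4 to 9 for hemocyte, 2 to 5 for ring gland, 4 to 7 for eye, 3 to 7 for glia and 3 to 5 for Notch targets. The fold change of Spps lay between -2.81 and -2.76 and that of pho between -1.78 and -1.62. Of named called genes, 33 of 52 in SppsKO, 43 of 68 in PhoKO and 9 of 11 in the direct comparison stayed called whichever library was left out.

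Hox genes that turned sign were not called. Quantile normalization gave 0.107 for Dfd, 0.0298 for Antp and 0.073 for Abd-B in SppsKO, and leaving out both shallow libraries gave 0.0246 for Abd-B in PhoKO. Leaving out single libraries gave -0.163 to 0.0302 for Abd-B in SppsKO, -0.0581 to 0.0365 for Dfd in PhoKO and -0.121 to 0.0726 for Abd-B in PhoKO.

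Replicate numbers are shared by the groups, and there was little sign that they pair the libraries. Of 9 pairs with the same number, 2 had residual correlations over 0.1 (range -0.377 to 0.11). No library of 9 correlated best with its own number in each of the other groups, though some did in 1 of them. With so few libraries per group, these correlations cannot exclude pairing. With the replicate number as a block, the counts were 449, 670 and 753 genes and 173 in both mutants, and the covariance was 0.0947. In that fit 4 lists were called in SppsKO, and 5 hemocyte, 4 eye and 4 glia members were called. Only SppsKO has a replicate 4, so the block also takes SppsKO 4 out of the comparison. The fold change of Spps (-2.79) and the covariance equal those without SppsKO 4, and the block leaves fewer degrees of freedom. Depth is known only relative to WT 1, so low genes are least certain in WT 3 and PhoKO 1.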

Other observations

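Signal and patterning genes moved singly. In PhoKO the ligand gene Wnt6 fell by 0.45 (SE 0.06, limma adjusted p = 0.00119), 1 of 22 segment polarity and ligand genes lower and 1 higher, with the same counts adjusted over the list alone. The higher gene, pyr, lost its limma call without WT 1, WT 2, SppsKO 1, SppsKO 2, PhoKO 1 or PhoKO 2 (highest adjusted p = 0.101). That call also ended without both shallow libraries. The list in SppsKO held 1 call, wg, which was lost without WT 1, among others, and 0 adjusted over the list alone. Cuticle genes rose for 2 of 19 in PhoKO, with Cpr66D up by 1.01 (SE 0.06), and for 1 in SppsKO, again Cpr66D (0.36, SE 0.06); adjusted over the list alone the counts were 3 and 1. Of 12 tracheal genes Osi7 fell in PhoKO (-0.92, SE 0.12), and the counts in both mutants were the same adjusted over the list alone. In SppsKO obst-A rose, and Osi7 (-0.41, SE 0.11, adjusted p = 0.0487) was called but lost its call whichever of the 10 libraries was left out (highest adjusted p = 0.149), with a pseudocount of 0.1 and under quantile normalization. The testis gene vis rose in SppsKO (1.09, SE 0.08, adjusted p = 4.16e-05), 1 of 4 listed, and adjusted over the list alone 1 rose and 1 fell (fry adjusted p = 0.019, camera adjusted p = 0.667). In PhoKO versus SppsKO limma called vis and achi of this list (adjusted p = 3.98e-05 and 0.00226), 1 higher and 1 lower. Whether fragments were shared between vis and achi was not tested. Of 6 stock marker genes ry alone was called in SppsKO, also over the list alone (fry adjusted p = 0.0169, camera adjusted p = 0.167), and by limma 0 in PhoKO (1 at an unadjusted p under 0.05). The JAK/STAT and JNK list held 1 call in SppsKO, egr (0.15, SE 0.04, adjusted p = 0.0405), lost without WT 1, among others, and by limma 0 adjusted over the list alone (6 at an unadjusted p under 0.05).

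Remaining lists are given as counts. Neuron genes had 1 of 20 lower in SppsKO, 0 adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.932 with an estimated correlation, fry adjusted p = 0.536; the camera call ended without WT 1, WT 3 or SppsKO 4 and under median-of-ratios scaling) and 1 higher in PhoKO, also over the list alone. These single calls, VAChT and Appl, ended without WT 1, among other libraries. Antimicrobial genes had 1 of 16 lower in SppsKO, but 6 adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0339, adjusted p = 0.932 with an estimated correlation, fry adjusted p = 0.0654; ended without WT 2 or SppsKO 4 and under median-of-ratios scaling), and 2 lower in PhoKO, also over the list alone, a count of 0 without WT 2, WT 3, SppsKO 2, SppsKO 3 or any PhoKO library. Cytosolic ribosomal protein genes had 3 of 83 higher and 1 lower in PhoKO, 2 and 1 adjusted over the list alone (camera adjusted p = 0.0171, adjusted p = 0.99 with an estimated correlation, fry adjusted p = 0.556; ended without WT 2 or PhoKO 1, without both shallow libraries and under quantile normalization; 1 higher without WT 2), and 0 in SppsKO (6 at an unadjusted p under 0.05). Salivary gland genes had 1 of 13 lower in PhoKO (camera adjusted p = 0.0177, adjusted p = 0.99 with an estimated correlation, fry adjusted p = 0.343; ended without WT 3 or PhoKO 3). Disc epithelium genes had 2 of 22 higher and 2 lower in SppsKO (3 and 2 adjusted over the list alone) and 1 higher in PhoKO (0 adjusted over the list alone). The number higher in SppsKO was 4 without PhoKO 1, 2 without WT 2 and 1 without any other library. The SppsKO calls of wg, rn and ap and the PhoKO call of fng ended without WT 1, among others for all but rn. Single calls in other lists each ended when any 1 of several libraries was left out. They were pgc among 6 germline genes in PhoKO (without WT 2, WT 3, PhoKO 2 or PhoKO 3), Eip74EF among 22 ecdysone genes in SppsKO (8 libraries), Hsp23 among 19 heat stress genes in PhoKO (7 libraries) and btd among 6 Sp family genes and Pho paralogs in PhoKO (6 libraries). The number of libraries is of the 10, each left out alone, and WT 2 was among them for all 4 genes. Adjusted over the list alone, 3 germline genes fell in PhoKO, 1 ecdysone gene in SppsKO and 1 heat stress gene in PhoKO, while in the Sp family 2 rose and 2 fell in PhoKO and 1 fell in SppsKO. By limma the same lists held 0 calls in the other mutant, with 1 germline, 1 ecdysone, 1 heat stress and 1 Sp family gene at an unadjusted p under 0.05. By limma sex composition genes had 0 of 4 called in either mutant, with 0 and 1 at an unadjusted p under 0.05. The single tested histone gene, His1:CG33840, rose in SppsKO (1.62, SE 0.11).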
